A study of Mus musculus with 2 samples.

How the data were processed

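Droplet single-cell RNA sequencing (10x Chromium, 3′ chemistry) was done on cells of the peritoneal cavity of germ-free mice, with 1 library for WT and 1 for Xbp1dIEC, each a pool of 4 male mice of 10 weeks. The deposited values are counts, that is UMIs per gene and cell barcode, as whole numbers without normalization. The submitters' processing notes name Cell Ranger 2.2.0, Seurat 2.3.0 and the build mm10; the gene annotation and any filter on barcodes are not given in the sources used here. Both libraries list the same 28692 genes. The lowest total per barcode was 2597 UMIs in WT and 2485 in Xbp1dIEC, so no barcode lay under the minimum of 500 UMIs set here. Barcodes with 500 or more UMIs, 200 or more genes and under 10% mitochondrial UMIs were kept, which left out 6 WT and 20 Xbp1dIEC barcodes for mitochondrial share. Doublets were called per library with scrublet as built into scanpy 1.11.5, with an expected rate of 5%, and 144 WT (2.32%) and 109 Xbp1dIEC barcodes were called and removed. Among cells kept, 521 in WT (8.60%) and 351 in Xbp1dIEC (5.74%) still carried marker genes of 2 lineages.

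Cells of both libraries were clustered together on 2000 variable genes without immunoglobulin variable segments, after scaling to 10000 UMIs per cell and a log transform. Clustering used 30 principal components, 15 neighbours and the Leiden method at resolution 1, in Python 3.11.15 with scanpy 1.11.5, igraph 0.11.9 and anndata 0.12.19. It gave 19 clusters. A cluster was named from marker lists that were fixed before the data were examined. At least 3 markers of a list had to be detected in 10% of the cluster's cells, at 25% or more of the level in the highest cluster. A cluster stayed unnamed if its top 10 genes held more markers of another list than of its own, or if it had under 20 cells. It was called mixed if 50% or more of its cells had genes of 2 lineages. These scoring rules, unlike the lists, were set and revised after the clusters and the class sizes per library had been seen. The earliest score, which relied on single detected markers, left most macrophage and B cell clusters unnamed. Then 3 versions of the rule were run: the strict one used throughout, a looser one, and one in which B-1 and B-2 markers did not count as a B cell cluster's own. All of them put the same 13 clusters in the same 5 classes in the clustering used here, but they differ in some alternative clusterings. Of the unnamed clusters, 13 and 17 were compared; cluster 15 was not, under a limit of 30% of cells with genes of 2 lineages that was set after the data were seen.

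Lists, comparisons, thresholds for genes and most alternatives were set before the data were examined. UMIs were summed per class and library and given as CPM with exact Poisson intervals. Log2 ratios of Xbp1dIEC over WT had 1 CPM added and exact conditional binomial intervals. Shares of cells had exact Clopper-Pearson intervals. With 1 library per genotype, cells are not replicates, so no p-value and no count of changed genes was computed, and all 95% intervals cover counting error only. Genes were named by a fixed ranking. In each class with 500 or more cells per library, the 12 highest and 12 lowest log2 ratios were taken among genes with 100 or more UMIs and 50 CPM in the higher library. In each other class with 100 or more cells per library, the 6 highest and 6 lowest were taken among genes with 30 or more UMIs and 50 CPM. Variable segments, ribosomal, mitochondrial and haemoglobin genes and unnamed gene models were left out, as were genes under 5% of their CPM in another class of the same library. The ranking gave 108 entries over 7 classes and clusters. Members of the gene lists, marker genes, immunoglobulin constant genes and Xbp1 were also named.

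For 24 fixed gene lists, the median log2 ratio over members with 10 or more UMIs was taken where 5 or more members were measured, which gave 155 medians. Each median was placed among 10000 random lists matched on expression in 20 bins, and its interval came from 1000 Poisson resamples. Symbols shared by several gene IDs were not used as members, which left out 2 of them. Cycling cells were those with 2 or more UMIs of the cell cycle list, and Igha cells those with 3 or more Igha UMIs, after each cell was thinned to 1000 UMIs; no cell was shallower. In simulated counts with 200 of 28692 genes changed, all 24 genes named in large macrophage-like and in B-1-like cells were truly changed, and 11 of 12 in T cell-like cells. The intervals covered the true ratio of 95.0% to 95.1% of unchanged genes, and of 90.5% to 100% of changed genes, lowest in large macrophage-like cells. The planted changes put the unchanged genes there at a log2 ratio of -0.16 through the shared total. The simulated counts varied by Poisson error only, with no difference between pools. They check the calculation and say nothing on whether genes named in the real data reflect genotype. Alternatives changed the filter on cells, the doublet step, the clustering, the naming rule, the scaling, the CPM added, the weighting of cells, the thinning and the minimum UMIs. Calculations used numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9. Exons and splicing were not analysed here.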

Results

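Cells of the peritoneal cavity were profiled by droplet single-cell RNA sequencing from germ-free mice, which carry no microbes. A wild-type (WT) library was compared with a library from Xbp1dIEC mice, in which Xbp1, a transcription factor of the unfolded protein response, is deleted in the intestinal epithelium. Each library pooled 4 male mice aged 10 weeks, per the labels, and 8700 cells were encapsulated for each. The files held 6204 barcodes and 56229330 UMIs for WT, and 6246 barcodes and 49703442 UMIs for Xbp1dIEC. The median was 8324 UMIs and 2144 genes per barcode in WT and 7280 UMIs and 1919 genes in Xbp1dIEC. A larger number of Xbp1dIEC barcodes took 5% or more of their UMIs from mitochondrial genes, 1153 against 425 in WT. After filtering and removal of doublets, 6055 WT and 6117 Xbp1dIEC cells were kept. With 1 library per genotype no difference has a replicate check and no test between genotypes was made; all intervals are 95% intervals that cover counting error only.

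The question of the first comparison was whether the makeup of the peritoneal cavity differs when the unfolded protein response is disturbed in the gut epithelium. B-1-like cells, the innate-like B cells that are a main source of natural antibody, were a larger share of the Xbp1dIEC library, and B-2-like cells, the conventional B cells, a smaller one. B-1-like cells were 1049 of 6055 in WT (17.3%, exact Clopper-Pearson interval 16.4 to 18.3) and 1422 of 6117 in Xbp1dIEC (23.2%, 22.2 to 24.3). The log2 ratio of Xbp1dIEC over WT was 0.42 (0.31 to 0.54). B-2-like cells were 635 (10.5%, 9.73 to 11.3) and 417 (6.82%, 6.20 to 7.48), a log2 ratio of -0.62 (-0.80 to -0.44), which was -0.38 when each B cell was classed by marker score. Of all cells in these B cell classes, 62.3% were B-1-like in WT (59.9 to 64.6) and 77.3% in Xbp1dIEC (75.3 to 79.2), a log2 ratio of 0.31. By marker score that ratio was 0.50, and with 1000 variable genes, 15 components and looser naming it was 0.58, with 0.68 for the B-1-like share of all cells. Under these settings 41.45% and 38.81% of WT B cells were B-1-like, against 58.46% and 58.17% in Xbp1dIEC. Whether B-1-like cells were most of the WT B cells thus depended on the setting. With doublets kept, the B-1-like share ratio was -0.15 (-0.34 to 0.04), because a B cell cluster of 1416 cells lost its name to 1 plasma cell gene among its top 10; under a looser naming rule, chosen after seeing the data, it was 0.50.

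Large macrophage-like cells, the resident macrophages marked by Gata6 and Timd4, were the most numerous class in both libraries. They were 3110 cells in WT (51.4%, 50.1 to 52.6) and 3051 in Xbp1dIEC (49.9%, 48.6 to 51.1), a log2 ratio of -0.04 (-0.11 to 0.03). At a finer resolution it was -0.41, and with a stricter filter on cells -0.44. Small macrophage or monocyte-like cells were 163 (2.69%, 2.3 to 3.13) and 275 (4.50%, 3.99 to 5.05), a log2 ratio of 0.74 (0.46 to 1.03). That ratio depended on the clustering: it was -1.44 when each library was clustered alone and 0.23 at a finer resolution. T cell-like cells were 167 (2.76%, 2.36 to 3.20) and 147 (2.40%, 2.03 to 2.82), with a log2 ratio of -0.20 (-0.53 to 0.13). With each library clustered alone it was 0.75. This class does not hold all cells with T cell genes, since such genes also led cluster 12, with 305 WT and 142 Xbp1dIEC cells. Clusters 12 and 16, whose cells carried genes of 2 lineages, took 6.31% of WT and 3.84% of Xbp1dIEC cells. Unnamed clusters took 9.07% and 9.32%. They were clusters 13, 15, 17 and 18. Cluster 13 was led by Cd209a, Mgl2 and Ear2, and cluster 15 also by Cd209a, with genes of 2 lineages in 39.2% of its cells. Cluster 17 was led by Ccl5, Nkg7 and Klrk1, and cluster 18 had 4 and 7 cells. Cluster 3, led by Folr2, Retnla and Cbr2, is the whole small macrophage or monocyte-like class. Cluster 13 had the same best list, also with 11 markers detected. It stayed unnamed because its top 10 genes held 3 markers of another list against 2 of its own. Class II antigen presentation genes summed to 11850 CPM in WT cluster 3 and 64990 CPM in WT cluster 13. The class name therefore does not settle which of these clusters holds small macrophages.

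**Figure D1:**
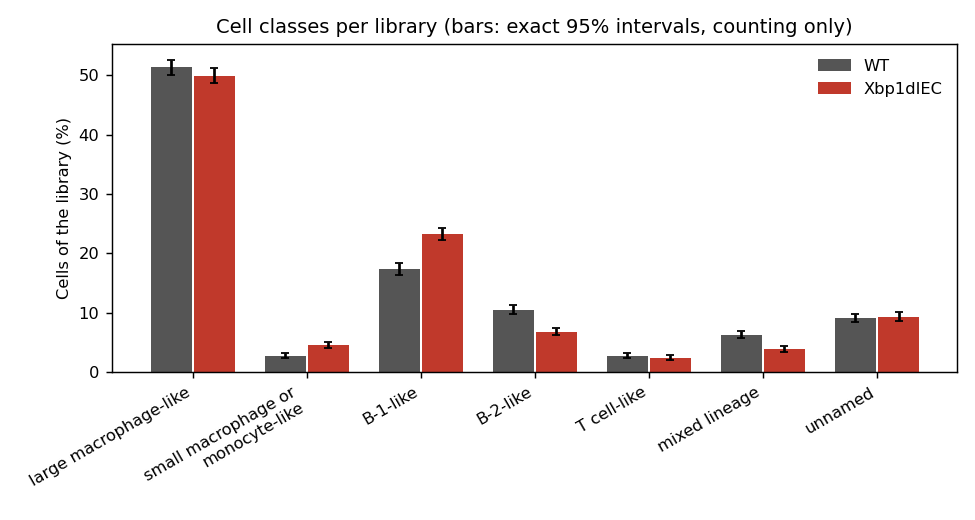
Share of kept cells (%, y axis) in each cell class (x axis) for WT (grey) and Xbp1dIEC (red), with bars for exact 95% intervals that cover counting error only. B-1-like cells were 17.3% in WT and 23.2% in Xbp1dIEC, B-2-like cells 10.5% and 6.82%, and large macrophage-like cells 51.4% and 49.9%.

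In large macrophage-like cells, Tgfb2, a ligand of the TGF-beta family, and Cxcl13, a chemokine that attracts B cells, were higher in the Xbp1dIEC library, and Arg1 (arginase) was lower. Tgfb2 was at 138 CPM (UMIs of the gene scaled to the total UMIs of the class) in WT (134 to 143) and 238 CPM in Xbp1dIEC (232 to 245), a log2 ratio of 0.78 (0.73 to 0.84). Cxcl13 was at 561 and 953 CPM (log2 ratio 0.76, 0.74 to 0.79), and Arg1 at 581 and 260 CPM (-1.16, -1.20 to -1.12). Among the other genes of the fixed ranking, Cmklr1, Herpud1, Cd93, Zfp36l1, Apoe, Csf3r, Rassf3, Trps1, C4b and Ski were higher. Their log2 ratios ran from 0.69 for Cmklr1, a chemerin receptor, to 0.40 for Ski. Apoe, a lipid carrier, was at 8811 and 12190 CPM. Beside the cell division genes below, Marco, a scavenger receptor, Adam8, Vim and Prdx4 were lower, with log2 ratios of -0.91, -0.83, -0.73 and -0.72. Cxcl13, Marco and Tgfb2 are among the leading genes of cluster 1 of this class, which held 480 WT and 856 Xbp1dIEC cells, and Apoe of cluster 4, which held 728 and 496. Median depth in the class was 9632 UMIs per cell in WT and 7679 in Xbp1dIEC.

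Cell division genes were lower as a group in Xbp1dIEC large macrophage-like cells. All 24 members of the cell cycle list were lower, with a median log2 ratio of -0.88 (-0.97 to -0.85). The median lay at percentile 0 among 10000 random lists of the same size matched on expression. Birc5, needed for chromosome segregation, was at 63.8 and 28.2 CPM (log2 ratio -1.15), Top2a at 63.0 and 33.4 CPM (-0.90), Ube2c at 58.3 and 29.1 CPM (-0.98) and Stmn1 at 185 and 93.2 CPM (-0.98). Gmnn, Dut and Cks1b, also tied to the cell cycle, had log2 ratios of -0.93, -0.92 and -0.81. After thinning every cell to 1000 UMIs, 365 of 3110 WT cells carried 2 or more UMIs of the list (11.7%, 10.6 to 12.9), against 191 of 3051 Xbp1dIEC cells (6.26%, 5.43 to 7.18). The log2 ratio of shares was -0.91 (-1.17 to -0.65), and the unthinned shares were 51.9% and 31.4%. With a stricter filter on cells the ratio of shares was -0.55 and the list median -0.51; there, clusters of 645 and 1093 cells whose best list was large macrophages stayed unnamed. Without clusters 9 and 10, led by cell cycle genes, the list median was -0.50. Over all cells kept, 8.47% in WT (7.78 to 9.20) and 5.51% in Xbp1dIEC (4.95 to 6.11) carried 2 or more UMIs after thinning. In B-1-like cells the shares were 4.96% (3.72 to 6.45) and 4.64% (3.61 to 5.87), and a difference was not detectable at this depth; with doublets kept the log2 ratio of these shares was 0.69.

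Other gene groups were lower in large macrophage-like cells of Xbp1dIEC. Low medians were common in this class, with 8 of 24 lists under percentile 1 and 0 over percentile 99. The glycolysis list had a median log2 ratio of -0.39 (-0.41 to -0.37, percentile 0), with 14 of 15 members lower; Ldha, lactate dehydrogenase, was at 608 and 415 CPM and Pkm at 442 and 324 CPM. All 11 members of the class II antigen presentation list were lower (median -0.31, -0.36 to -0.24, percentile 0.16, and -0.20 with 10 CPM added), among them H2-Ab1 at 129 and 93.2 CPM. The list's summed level in WT was 1822 CPM here, against 25980 CPM in B-1-like cells and 64990 CPM in cluster 13. Free RNA or doublets could give such levels, and this was not tested. All 6 measured immunoglobulin constant genes, which belong to B cells, were lower here too (median -0.43, -0.52 to -0.37), with Igkc at 136 and 98.9 CPM. Lists named for other cell types, B-1 identity, B-2 identity and naive T, had medians of -0.24, -0.33 and -0.29 in this class. Their summed levels here were 3084, 1897 and 1714 CPM in WT, and the B-1 identity list holds Vim, a gene of the ranking above. A list's name thus does not make all of its genes foreign to this class. A summed level can rest on few members, however, and does not show that typical members belong here. Ighd, a B-2 identity member, was at 5.8 and 3.6 CPM, and its WT level was 0.764% of that in the highest other class. With 10 CPM added the B-2 identity and naive T medians were -0.079 and -0.040. The unfolded protein response list had a median of -0.16 (-0.22 to -0.10, percentile 6.70), with 15 of 20 members lower. Within it, Pdia6 and Calr, chaperones of the endoplasmic reticulum, had log2 ratios of -0.51 and -0.35. Herpud1, a gene of protein degradation at that organelle, was at 51.3 and 76.0 CPM (0.56).

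Type I interferon response genes were lower in the Xbp1dIEC library, with the lowest list median in small macrophage or monocyte-like cells. There the median log2 ratio was -1.06 (-1.30 to -0.92, percentile 0) and 17 of 17 measured members were lower. Irf7, a transcription factor that amplifies interferon production, was at 77.7 and 32.0 CPM (log2 ratio -1.25, -1.75 to -0.82). Oasl2 was at 53.3 and 17.3 CPM (-1.57, -2.25 to -1.02), Rtp4 at 146 and 66.7 CPM (-1.12), and Cmpk2 at 5.27 and 5.25 CPM. The median was -0.73 (-0.98 to -0.48) in cluster 13, with 17 of 17 members lower, and -0.46 (-0.52 to -0.37) in large macrophage-like cells, with 17 of 20 lower. In lymphocytes it was -0.24 (-0.40 to -0.13) in B-1-like, -0.26 (-0.56 to -0.05) in B-2-like and -0.40 (-0.71 to -0.10) in T cell-like cells, and -0.25 (-0.54 to 0.13) in cluster 17. With 10 CPM added, the median was -0.44 in cluster 13, -0.28 in large macrophage-like and -0.091 in B-1-like cells. The interferon gamma list was also lower in small macrophage or monocyte-like cells (median -0.56, -0.81 to -0.39, 14 of 14 members lower). With a stricter filter on cells the type I median in large macrophage-like cells was -0.18. Cluster 4 of that class, with 728 WT and 496 Xbp1dIEC cells, counts the interferon genes Rtp4 and Ifi204 among its leading genes. Within the clusters of the class, a comparison chosen after the class value was seen, the median was -0.44 (-0.61 to -0.36) in cluster 4, and the interval lay below 0 in 5 of 7 clusters. In clusters 9 and 10, led by cell cycle genes, it was 0.02 (-0.25 to 0.18) and -0.08 (-0.48 to 0.11). In small macrophage or monocyte-like cells, class II antigen presentation genes were lower too, with 10 of 11 members lower (median -0.31, -0.71 to -0.26). AF251705, a leading gene of clusters 13 and 15, was the lowest gene of the ranking there.

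**Figure D2:**
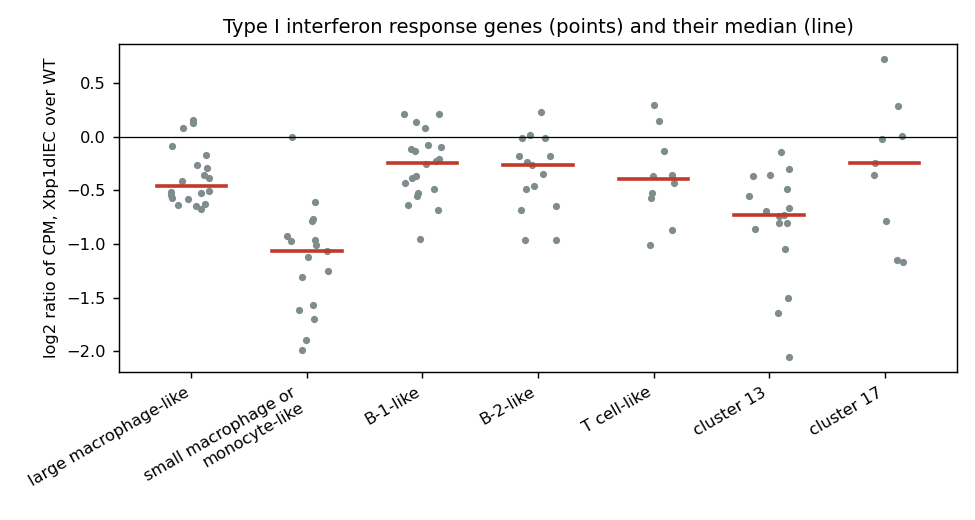
Log2 ratio of CPM, Xbp1dIEC over WT (y axis), of each measured type I interferon response gene (points) in each cell class or cluster (x axis), with red lines for the list median. The medians were -1.06 in small macrophage or monocyte-like cells, -0.73 in cluster 13 and -0.46 in large macrophage-like cells.

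In small macrophage or monocyte-like cells, Apoc4 and Ccl24 were among the higher genes of the ranking in Xbp1dIEC. Apoc4, an apolipoprotein, was at 11.2 CPM in WT (6.52 to 17.9) and 63.0 CPM in Xbp1dIEC (52.3 to 75.4), a log2 ratio of 2.39 (1.76 to 3.32). Ccl24, an eosinophil chemoattractant, was at 570 and 1136 CPM (0.99), and Cd93, Igfbp4, Cmklr1 and F5 had log2 ratios of 1.26, 1.02, 0.94 and 0.93. Beside the interferon genes, AF251705, Fbxo6, Slc2a6 and Phf11b were the lower genes of the ranking, from -1.72 to -1.20. The large macrophage programme had 10 of 19 members higher, with Alox15 at 378 and 708 CPM, Prg4 at 637 and 938 CPM, and Marco at 190 and 122 CPM; its median of 0.21 had an interval of -0.12 to 0.29. The list of IgA-promoting cytokines had 3 of 5 measured members higher (median 0.46, -0.02 to 0.70, and 0.71 with doublets kept), among them Cxcl13 at 124 and 182 CPM. Glycolysis genes had a median of -0.35 (-0.45 to -0.25), with 14 of 15 lower. The lipid and lysosome list did not stand apart from random lists there (median -0.12, percentile 33.4), and its summed level was 19540 and 24670 CPM. In cluster 13, Cd209d, a C-type lectin, was at 29.6 and 78.0 CPM (1.37) and Mrc1, the mannose receptor, at 102 and 174 CPM (0.76), with Toporsos, Klrb1b, Eps15 and Nudcd3 from 0.89 to 0.76. Rtp4, Ly6c2, Ltb, Pglyrp1, Ptp4a3 and Stom were lower, from -1.50 to -0.87. All 8 inflammatory cytokine genes measured in cluster 13 were lower (median -0.46, -0.78 to -0.26), with Saa3 at 219 and 104 CPM.

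In B-1-like cells, the question was whether gut epithelial loss of Xbp1 goes along with a different state of the cells that can give rise to IgA. The chaperone genes Hsph1 and Hsp90aa1, Lifr and the cell cycle and survival genes Ccnd2 and Pim1 were higher in Xbp1dIEC. Cd24a, a surface glycoprotein of developing and conventional B cells, was lower. None of the 24 fixed lists is one of chaperones, and the 18-gene list used further below was added after the data were seen. Hsph1, a heat shock protein, was at 19.6 CPM in WT (16.8 to 22.7) and 68.5 CPM in Xbp1dIEC (64.2 to 73.1), a log2 ratio of 1.75 (1.57 to 2.05). Lifr, a cytokine receptor, was at 29.4 and 83.6 CPM (1.48), Cited2 at 39.3 and 108 CPM (1.43), Pim1 at 217 and 456 CPM (1.07) and Ccnd2, cyclin D2, at 263 and 500 CPM (0.93). Hsp90aa1 was at 360 and 617 CPM (0.78), and Prkar2b, Gbp7, Lmo7, Chordc1, Hist1h2bc and Zcwpw1 had log2 ratios from 1.23 to 0.78. Cd24a was at 379 and 178 CPM (-1.09, -1.17 to -1.02), Ccr7, a receptor for homing to lymph nodes, at 93.9 and 52.5 CPM (-0.83), and Fcmr, the IgM Fc receptor, at 295 and 168 CPM (-0.81). Ms4a6c, Hvcn1, H2-Q7, Anxa2, Wdfy1, Tnfaip8, Ahnak2, Anxa5 and Grap had log2 ratios from -0.98 to -0.61. Most WT cells of the class lay in cluster 5 (648 WT and 432 Xbp1dIEC cells, led by Ahnak2, Zcwpw1 and Zbtb32) and most Xbp1dIEC cells in cluster 11 (358 and 927, led by Fbxw13 and Prkar2b). Ccr7 and Fcmr are among the leading genes of the B-2-like cluster, and Anxa2 is a member of the B-1 identity list. Within each of clusters 5 and 11, 24 of the 24 named genes had the direction they had in the class. The genes were picked from the class that these clusters mostly make up, so the shared direction is no independent support. Several ratios were smaller within the clusters, so the class values partly reflect the different clusters. Lifr had 0.57 and 0.91, Fcmr -0.30 and -0.58, Anxa2 -0.15 and -0.52, and Ahnak2 -0.24 and -0.18, and the intervals of Anxa2 in cluster 5 and of Ahnak2 in cluster 11 included 0. Hsph1 had 1.43 and 1.67, and Cd24a -0.58 and -1.12.

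**Figure D3:**
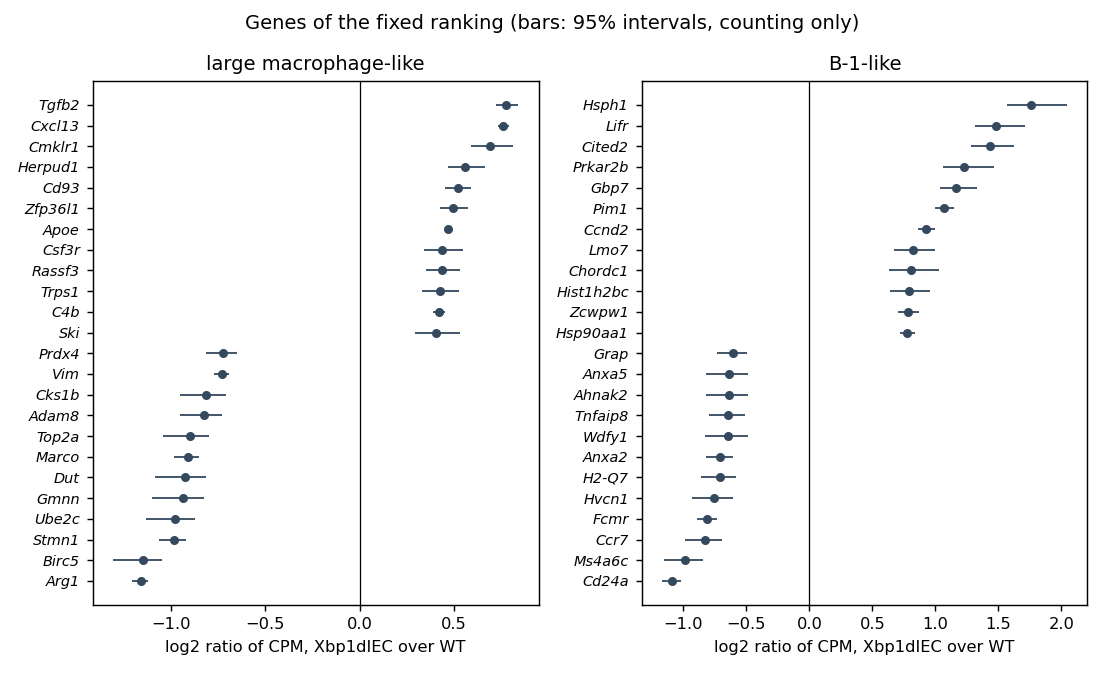
Log2 ratio of CPM, Xbp1dIEC over WT (x axis), of the 24 genes of the fixed ranking (y axis) in large macrophage-like cells (left) and B-1-like cells (right), with bars for 95% intervals that cover counting error only. Tgfb2 at 0.78 and Arg1 at -1.16 stand at the ends on the left, and Hsph1 at 1.75 and Cd24a at -1.09 on the right.

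Among gene groups of B-1-like cells, the unfolded protein response list was slightly higher in Xbp1dIEC. Lists of antigen presentation, activation, B-2 identity and B-1 identity had medians below 0. A low median was common in this class, with 12 of 23 lists under percentile 1 and 1 over percentile 99. The unfolded protein response median was 0.12 (0.07 to 0.23, percentile 99.7), with 17 of 20 members higher. Hspa5, the main chaperone of the endoplasmic reticulum, was at 119 and 168 CPM (0.49), Manf at 132 and 203 CPM (0.61) and Sdf2l1 at 51.9 and 78.9 CPM (0.59). Within clusters 5 and 11 the list's medians were 0.24 and 0.19. The list was not higher in B-1-like cells alone: in cluster 13 its median was 0.15 (0.04 to 0.26, percentile 99.85), with 14 of 19 members higher. For class II antigen presentation 10 of 11 members were lower (median -0.30, -0.35 to -0.26, and -0.20 with doublets kept), with H2-Ab1 at 2552 and 1935 CPM; within the clusters the medians were -0.14 and -0.35. For B-2 identity 11 of 12 were lower (median -0.30, -0.37 to -0.19), and within the clusters the medians were -0.26 and -0.44. For B-1 identity 9 of 16 were lower (median -0.17, -0.25 to -0.01, percentile 0.97), and within the clusters the medians were -0.05 and 0.09. The B cell activation list had 15 of 21 members lower (median -0.36, -0.41 to -0.13). Nfkbia was at 257 and 181 CPM and Cd83 at 46.8 and 31.8 CPM. Among the 6 higher members, Il2ra was at 3.99 and 11.9 CPM and Ccnd2 at 263 and 500 CPM. The list's summed level was 977.5 CPM in WT and 1094 CPM in Xbp1dIEC, so its total went the other way. Its medians within clusters 5 and 11 were -0.04 and -0.20, and the class median was -0.10 with 10 CPM added or with doublets kept. The glycolysis median was -0.21 in the class and 0.00 and -0.02 within the clusters. The cell cycle median was -0.20 (-0.29 to -0.10) in the class, -0.04 and -0.46 within the clusters, -0.10 with 10 CPM added, 0.25 with doublets kept and 0.00 with a stricter filter on cells. Lists of large macrophage, complement, and lipid and lysosome genes had medians of -0.23, -0.30 and -0.27. Their summed levels in WT were 243, 978 and 1332 CPM here, against 10690, 25960 and 17700 CPM in large macrophage-like cells. The large macrophage median was -0.053 with doublets kept and -0.46 without cells of 2 lineages, and the other medians were -0.14 each with 10 CPM added.

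The series is about an IgA response, and Igha, the IgA heavy chain constant gene, did not differ detectably between the libraries in B-1-like cells. It was at 8.97 CPM in WT (81 UMIs, 7.12 to 11.2) and 8.97 CPM in Xbp1dIEC (121 UMIs, 7.44 to 10.7), a log2 ratio of 0.00 (-0.42 to 0.42). Without thinning, 3 of 1049 WT and 3 of 1422 Xbp1dIEC B-1-like cells had 3 or more Igha UMIs. After thinning to 1000 UMIs there were 0 in both, which at this level of the gene sets no limit on the share of IgA cells. With 1 or more UMIs the thinned shares were 0.763% (0.330 to 1.5) and 0.844% (0.437 to 1.47), and unthinned they were 6.67% and 7.53%. In T cell-like cells, which should lack the gene, 0 of 167 and 0 of 147 had an Igha UMI, with exact intervals up to 2.185% and 2.478%. In large macrophage-like cells the unthinned shares were 0.161% and 0.0328%. Median depths were 7206 and 7726 UMIs in B-1-like, 3371 and 3428 in T cell-like, and 9632 and 7679 in large macrophage-like cells. The IgA switching and secretion list had a median of 0.00 (-0.08 to 0.11, percentile 63.6), with 8 of 15 members higher. Jchain, which joins IgA and IgM polymers, was at 37.6 and 19.1 CPM (-0.95, -1.22 to -0.74), Ighm at 3470 and 2910 CPM (-0.25), Ighd at 210 and 163 CPM (-0.36, and -0.22 with doublets kept) and Igkc at 10230 and 8554 CPM (-0.26, and -0.070 with doublets kept). In B-2-like cells Igha was at 5.77 and 7.29 CPM and Igkc at 12590 and 12550 CPM. No cluster was named as plasma cells.

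Xbp1 itself was measured in every class, but its deletion is in the gut epithelium, so its level in peritoneal cells checks nothing about the labels. It was at 32.5 CPM in WT and 44.4 CPM in Xbp1dIEC in B-1-like cells (log2 ratio 0.44, 0.25 to 0.66, and 0.22 with doublets kept) and at 108 and 117 CPM in large macrophage-like cells (0.12, 0.05 to 0.20). Intervals included 0 in B-2-like (31.7 and 31.0 CPM, -0.03), T cell-like (23.0 and 40.9 CPM, 0.81) and small macrophage or monocyte-like cells (98.1 and 116 CPM, 0.24). They also did in cluster 13 (88.2 and 92.7 CPM, 0.07) and cluster 17 (14.3 and 21.4 CPM, 0.55).

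In T cell-like cells, the effector genes Ccl5 and Il2rb were among the higher genes of the ranking in Xbp1dIEC, and the list of naive T cell genes was lower. Ccl5, a chemokine of effector T cells, was at 305 CPM in WT (263 to 353) and 791 CPM in Xbp1dIEC (717 to 870), a log2 ratio of 1.37 (1.12 to 1.63). Ly6c2, Lmna, Tcrg-C1, Il2rb and Clcn3 had log2 ratios from 1.98 to 1.29, on 14 to 22 UMIs in WT. Xpa, Mrpl9, Ppp3r1, Ppa1, Copa and Ctsa were lower, from -1.24 to -1.12, on 12 to 16 UMIs in Xbp1dIEC. Ccl5, Ly6c2 and Il2rb are leading genes of cluster 17, and Ccl5 in T cell-like cells was at 7.64% of its level there. The T effector and regulatory list had 7 of 11 members higher, and its median of 0.24 had an interval that included 0 (-0.01 to 0.68). The naive T list had a median of -0.22 (-0.38 to -0.08, percentile 0.155), with 7 of 9 members lower; Ccr7 was at 384 and 233 CPM. Markers of other cells moved with these groups: class II antigen presentation had a median of -1.17 (-1.50 to -0.80, and -0.61 with doublets kept) in T cell-like cells and Igkc was at 322 and 110 CPM. In cluster 17, Gzmb and Gzma, the cytotoxic granzymes, were higher, at 19.1 and 83.6 CPM (2.08, 1.18 to 3.19) and 218 and 647 CPM (1.57, 1.28 to 1.87). S100a4, Ly6d, Klra9 and Btbd1 had log2 ratios from 1.70 to 1.22. In Xbp1dIEC, S100a4 and Ly6d were at 6.45% and 5.03% of their level in the highest other class, close to the limit of 5%. Golga4, Tmem256, Dpm1, Fam78a, Upf3b and Rnf5 were lower, from -1.55 to -1.14. The naive T median was -0.33 (-0.55 to -0.18) there, and that of T effector and regulatory genes 0.10 (-0.03 to 0.33).

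In B-2-like cells, chaperone genes were again among the higher genes of the ranking. Hsph1 was at 28.5 CPM in WT (22.9 to 35.1) and 54.7 CPM in Xbp1dIEC (44.0 to 67.2), a log2 ratio of 0.92 (0.50 to 1.38). Stip1 and Ptges3, which act with Hsp90, were at 51.0 and 83.9 CPM (0.71) and 89.4 and 129 CPM (0.53). Bcl7b, Dennd4a and Sfn had log2 ratios of 0.71, 0.58 and 0.57. Rnf114, Yipf3, Pcbd2, Rfc1, Cdk11b and Crlf2 were lower, from -0.68 to -0.55. The unfolded protein response list had a median of 0.04 (-0.06 to 0.15), with 11 of 19 members higher, and the interferon gamma list one of -0.25 (-0.39 to -0.04), with 12 of 15 lower.

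Positions of the genes that lead these comparisons, from the GENCODE annotation of the same build (mm10, GRCm38) matched by gene ID, were as follows. Xbp1 lies on chromosome 11 from 5520659 to 5525893, Irf7 on chromosome 7 from 141262706 to 141266481, and Cxcl13 on chromosome 5 from 95956951 to 95961068. Tgfb2 lies on chromosome 1 from 186622792 to 186705989 and Arg1 on chromosome 10 from 24915221 to 24927484. Hsph1 lies on chromosome 5 from 149614287 to 149636376, Cd24a on chromosome 10 from 43578284 to 43584265, and Igha on chromosome 12 from 113254830 to 113260236. UMIs were counted per gene from its 3′ end, and exons were not analysed apart.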

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

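The tests below of interferon genes, of depth, of immediate early genes and of pool differences were chosen after the result was seen; those of mitochondrial share and of handling stress were set before their values were known.

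Clusters 12 and 16, which no comparison of genes between genotypes uses, held 6.31% of WT and 3.84% of Xbp1dIEC cells. In cluster 12, T cell genes such as Trbc2 and Cd3g were found with B cell genes, and 97.1% of its cells carried genes of 2 lineages. It had 305 WT and 142 Xbp1dIEC cells, a log2 ratio of shares of -1.12 (-1.42 to -0.83). No explanation was tested for it.

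Type I interferon genes were lower in Xbp1dIEC, with a median of -1.06 in small macrophage or monocyte-like cells. Library scaling is argued against, since with median-of-ratios scaling the median was -1.01 (-1.24 to -0.87). Free RNA from large macrophage-like cells is argued against as well, because the summed CPM of the list in WT small macrophage or monocyte-like cells was 180% of that in large macrophage-like cells. Within the small macrophage or monocyte-like class, class II genes and AF251705, which mark neighbouring clusters, were lower as well, so a different makeup of that class stays open, and in large macrophage-like cells the median was -0.18 with a stricter filter. With 1 library per genotype, a difference between the pools of mice or their handling cannot be told apart from an effect of genotype, so a lower interferon tone through the gut epithelium may only be put as a hypothesis.

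Fewer large macrophage-like cells of Xbp1dIEC carried cell cycle UMIs. Lower depth is argued against as the whole cause, since after thinning to 1000 UMIs the log2 ratio of shares was -0.91 (-1.17 to -0.65). The larger number of cells with a high mitochondrial share is argued against too, with -0.88 (-1.16 to -0.61) among cells under 5%. When the whole clustering was redone with the stricter filter, the ratio was -0.55 (-0.84 to -0.27) in a class that lacked some macrophage clusters. A difference between pools, with 1 library per genotype, cannot be told apart from lower proliferation of resident macrophages, which could be an effect of genotype.

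Chaperone genes such as Hsph1 were higher in Xbp1dIEC B cells. Handling stress on every cell of the pool is argued against by large macrophage-like cells. There an 18-gene chaperone list, added after the data were seen, had a median of -0.0745 (-0.11 to -0.03). Its medians were 0.65 (0.58 to 0.71) in B-1-like and 0.48 (0.33 to 0.52) in B-2-like cells. Since the list came after the B cell genes were seen, these B cell medians are no independent support. The list's median was also above 0 in T cell-like cells (0.28, 0.08 to 0.40), cluster 17 (0.37, 0.21 to 0.54) and the myeloid cluster 13 (0.19, 0.15 to 0.39). It was at 0.02 (-0.11 to 0.15) in small macrophage or monocyte-like cells, so handling stress that acts on some cell types stays open. An immediate early response to dissociation is argued against by the immediate early and dissociation list without its chaperones, which had a median of -0.0905 (-0.21 to -0.04) in B-1-like cells, with 3 of 15 members higher. That value is weak, since low list medians were common in this class, with 12 of 23 under percentile 1. The chaperones were left out, so a dissociation response limited to them stays open. An effect of genotype on B cells and a difference between pools may both be the source, and neither was tested.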

How the results depend on the processing

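The removal of cells with genes of 2 lineages, the looser and first naming of clusters the omission of clusters 9 and 10 and the comparison within clusters were chosen after seeing the data; the other alternatives were set before. Values are log2 ratios of Xbp1dIEC over WT or list medians of them, with the reported value in parentheses. Over the alternatives, 619 values of named genes moved by less than their counting interval, 101 moved further and 0 reversed. For lists the numbers were 902, 92 and 6, for shares of cells 109, 26 and 4, and for Xbp1 and immunoglobulin genes 87, 14 and 0. Gene and list values were recomputed only for scaling, CPM added, weighting of cells, doublets kept, the stricter filter and the removal of cells or clusters. They were not recomputed under the other clusterings or naming rules, so their counts say nothing on those settings. Without the minimum of UMIs and CPM, 4 of 24 genes in large macrophage-like, 2 of 24 in B-1-like, 1 of 12 in small macrophage or monocyte-like cells and 0 of 12 in each other class or cluster stayed among the highest and lowest, so the names depend on that minimum. No paired analysis was possible because each genotype is 1 library. Depth limits what can be seen in T cell-like cells, of which there were 167 and 147 at medians of 3371 and 3428 UMIs. Unless a cause is given, the cause was not tested.

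Shares of cells depended on the clustering. With each library clustered alone, under all 3 naming versions, the share ratio was 0.75 (-0.20) for T cell-like and reversed to -1.44 (0.74) for small macrophage or monocyte-like cells. With the first naming, no WT cell was then B-1-like and no ratio was had. At resolution 2 the ratio was 0.23 (0.74) for small macrophage or monocyte-like cells under both namings, and -0.41 (-0.042), or -0.29 with looser naming, for large macrophage-like cells. With 1000 variable genes and 15 components, these ratios were 0.25 (0.74) and -0.15 (-0.042) under both namings. Looser naming there gave 0.68 (0.42) for B-1-like cells and 0.58 (0.31) for the B-1 share of B cells. Without a filter, small macrophage or monocyte-like cells had 0.37 (0.74) under both namings. Clustering without cycle, early, interferon and immunoglobulin genes gave 0.55 (0.42) for B-1-like cells and 0.44 (0.31) for the B-1 share of B cells. Marker scores for B cells gave 0.61 (0.42) for B-1-like cells, -0.38 (-0.62) for B-2-like cells and 0.50 (0.31) for the B-1 share of B cells. With a minimum of 1 UMI, Igha shares of B-1-like cells were 0.763% in WT and 0.844% in Xbp1dIEC (0 in both).

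With doublets kept, the B-1-like share reversed to -0.15 (0.42), because a B cell cluster lost its name. In the B-1-like cells left, the cycling share was 0.69 (-0.095), and cell cycle reversed to 0.25 (-0.20). Xbp1 was at 0.22 (0.44), Ighd at -0.22 (-0.36) and Igkc at -0.070 (-0.26). Class II antigen presentation was at -0.20 (-0.30), B cell activation at -0.098 (-0.36), immunoglobulin constant at -0.17 (-0.23), large macrophage programme at -0.053 (-0.23), and complement and lipid lists at -0.16 each (-0.30 and -0.27). Large macrophage-like cells had a share ratio of -0.24 (-0.042), cell cycle -0.72 (-0.88), class II -0.21 (-0.31) and glycolysis -0.44 (-0.39). T cell-like cells had class II -0.61 (-1.17) and immunoglobulin constant -0.37 (-0.90), and small macrophage or monocyte-like cells IgA-promoting cytokines 0.71 (0.46).

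With the stricter filter, no small macrophage or monocyte-like class was formed and unnamed clusters took 17.2% of WT and 30.6% of Xbp1dIEC cells. Large macrophage-like cells had a share ratio of -0.44 (-0.042), cycling share -0.55 (-0.91), cell cycle -0.51 (-0.88), type I interferon -0.18 (-0.46) and class II -0.38 (-0.31). B-1-like cells had Ighm -0.28 (-0.25), Ighd -0.25 (-0.36) and Igkc -0.18 (-0.26), and cell cycle reversed to 0.0015 (-0.20). T cell-like cells had class II -0.56 (-1.17) and immunoglobulin constant -0.47 (-0.90). Without cells of 2 lineages, T cell-like cells had -0.64 and -0.47 for these lists. B-1-like cells then had Ighm -0.20, Igkc -0.17, immunoglobulin constant -0.17 and large macrophage programme -0.46 (-0.23), and B-2 identity in cluster 13 reversed to 0.11 (-0.25). Without clusters 9 and 10, large macrophage-like cells had cell cycle -0.50 (-0.88), since cycling cells were left out, type I interferon -0.55 and immunoglobulin constant -0.36.

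With 10 CPM added, which shrinks low genes by construction, B-1-like cells had cell cycle -0.10 (-0.20), type I interferon -0.091 (-0.24), B cell activation -0.10 (-0.36), immunoglobulin constant -0.19 (-0.23), and complement and lipid lists -0.14 each. Large macrophage-like cells had cell cycle -0.61, type I interferon -0.28, class II -0.20, immunoglobulin constant -0.30, B-2 identity -0.079 (-0.33) and naive T -0.040 (-0.29). Type I interferon was at -0.44 (-0.73) in cluster 13 and -0.73 (-1.06) in small macrophage or monocyte-like cells, where interferon gamma was at -0.39 (-0.56). As a mean over cells, B-1-like cells had Igkc -0.20, immunoglobulin constant -0.20 and large macrophage programme -0.44 (-0.23). The immunoglobulin constant list was at -0.55 (-0.90) in T cell-like cells, and in large macrophage-like cells cell cycle was at -0.79 and type I interferon at -0.56 (-0.46).

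Under median-of-ratios scaling, B-1-like cells had Ighm -0.23, Igkc -0.23 and immunoglobulin constant -0.20, and B-2-like cells Igkc 0.021 (-0.0039). Large macrophage-like cells had cell cycle -0.82, immunoglobulin constant -0.36 and glycolysis -0.33. Class II in cluster 13 reversed to 0.030 (-0.038), and the unfolded protein response in small macrophage or monocyte-like cells was at 0.044 (-0.018). With a total without ribosomal, mitochondrial and immunoglobulin genes, B-1-like cells had Ighm -0.20, Igkc -0.20, class II -0.24 and immunoglobulin constant -0.17, and oxidative phosphorylation reversed to 0.027 (-0.028). Cell cycle was at -0.84, immunoglobulin constant at -0.37 and glycolysis at -0.33 in large macrophage-like cells. Class II in cluster 13 reversed to 0.027 (-0.038), and the unfolded protein response in small macrophage or monocyte-like cells was at 0.045 (-0.018).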

Other observations

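The within-cluster values below were chosen after the class values were seen.

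Cluster 14, the third B-1-like cluster, was led by cell cycle genes and held 43 WT and 63 Xbp1dIEC cells. The IgA switching and secretion list had medians of 0.01 within cluster 5 and -0.03 within cluster 11, and the type I interferon list -0.19 and -0.32. Clusters 9 and 10 of the large macrophage-like class held 283 and 212 WT cells against 121 and 102 Xbp1dIEC cells.

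Some fixed lists had medians near 0 in large macrophage-like cells. They were 0.03 for the large macrophage programme, 0.07 for IgA-promoting cytokines, 0.00 for alternative activation, 0.05 for immediate early genes, 0.09 for IgA switching and secretion, -0.03 for inflammatory cytokines, -0.06 for homing and migration and -0.07 each for complement and clearance and for B cell activation. Cholesterol synthesis had 0.07, hypoxia -0.08, and T effector and regulatory -0.10 over 6 measured members. Medians further from 0 were -0.14 for oxidative phosphorylation (percentile 16.8 among random lists), -0.20 for lipid and lysosome (percentile 2.33) and -0.18 for interferon gamma response (percentile 2.64). The summed level of the lipid and lysosome list was 17700 and 20170 CPM. In B-1-like cells the medians were -0.05 for immediate early genes, -0.13 for interferon gamma response, -0.10 for homing and migration, -0.17 for B-1 identity, -0.23 for immunoglobulin constant genes, -0.03 for oxidative phosphorylation (0.027 with a total without ribosomal, mitochondrial and immunoglobulin genes), -0.19 for cholesterol synthesis and -0.02 for hypoxia. Within clusters 5 and 11 of that class the B-1 identity medians were -0.05 and 0.09. In cluster 17 the B-1 identity list had 0.37 and B cell activation 0.43. In T cell-like cells B-1 identity had 0.42 (0.18 to 0.76, percentile 99.95), while Igkc was lower there, at 322 and 110 CPM. Some B cell genes were higher in cluster 17, with Igkc at 208 and 315 CPM (log2 ratio 0.59, 0.26 to 0.94). Iglc3 was at 22.3 and 52.5 CPM and Ly6d at 36.6 and 117 CPM. In Xbp1dIEC these levels of Igkc, Iglc3 and Ly6d were 2.51%, 4.02% and 5.03% of those in the highest other class. Free RNA or doublets could give such levels, and this was not tested. Ighm was at 232 and 231 CPM and Iglc1 at 22.3 and 13.6 CPM. Of 6 immunoglobulin constant genes measured in cluster 17, 3 were higher (median 0.14, -0.18 to 0.69).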
